A study of Oryza sativa Japonica Group with 8 samples.

How the data were processed

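Inflorescence meristems of rice (Oryza sativa Japonica Group, cultivar Nipponbare, the cultivar from which the IRGSP reference sequence was made) were profiled by RNA sequencing in an osg1l2 single mutant and in a wild type control. Per the labels' protocols, plants grew in long days of 16 h light at 28°C and 8 h dark at 26°C and were dissected after 12 days in short days of 12 h light and 12 h dark, at 70% humidity. RNA was extracted with a plant column kit and libraries were made from cDNA with an Illumina preparation kit, per the labels' protocols. Strandedness is not given in the sources used here, so reads of a gene and of an antisense partner cannot be separated. The design text describes the 4 replicates of each genotype as independent, without saying what was separate, so p-values measure the spread between these libraries.

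The authors deposited 2 tables. The first holds one FPKM value per gene for each of the 8 libraries, with 37859 RAP gene identifiers. FPKM is fragment abundance divided by gene model length and library size, as scaled by the authors. The genome build is IRGSP-1.0, per the submitters' processing notes. The aligner and the quantification program are not given in the sources used here. The FPKM values include positive values far smaller than a single read could give, so they are estimates, whole reads were not recovered, and the sequencing depth of the libraries is unknown. No interval or detection floor that needs a depth is therefore given. An FPKM of exactly 0 can be a failed estimate, and such genes are described as listed at 0.

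The second table, with 37619 entries, holds the authors' own comparison. Per the file headers it gives 1 value per genotype, a log2 fold change and a q-value. The genotype values, treated here as a score because the deposited header names no unit, lay at a median of 1.62 times the mean FPKM of the wild type libraries (quartiles 1.47 and 1.96), so the 2 tables are on different scales. The deposited log2 fold change equals log2 of the osg1l2 value over the wild type value wherever both are above 0. It is written as 65535 in the 2218 entries where exactly 1 genotype is 0. The test behind the deposited q-value, and how libraries were combined, is not given in the sources used here.

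From the FPKM table, genes with a mean of at least 1 FPKM over the 8 libraries were tested (18254 genes). Values were transformed to log2(FPKM + 1), which understates the change of low genes, and the genotypes were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior, two-sided tests and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. All fold changes are osg1l2 over wild type on the log2(FPKM + 1) scale. The procedure was tested on simulated data with the means and spreads of the same 18254 genes. Of 200 genes changed by 1 on the log2 scale, 95.0% were recovered with 10 false calls, and of 200 genes changed by 2, 100% were recovered with 9 false calls. Smaller changes, an outlying library and correlation between genes were not simulated, so these rates do not cover them. Tables were joined and random placements drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9.

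The deposited tables do not pair identifiers with gene names. The reference gene table used here, built on the ASM3414082v1 assembly, contained 1 of the 37859 identifiers, without a gene symbol, and none of its coordinates were used. The 30 gene lists fixed before the data were examined (the ALOG family, meristem homeobox genes, MADS-box genes, hormone pathways, cell cycle, markers of leaf, vascular and epidermal tissue, stress and others) therefore had no members that could be tested. The expression of OsG1L2 was not analysed here for the same reason, so the genotype labels were not checked against the targeted gene. The rule for naming genes, also fixed before the data were examined, asked for the largest changes among called genes with a product description. It was applied without the description, to the 2 largest rises and the 2 largest falls among called genes whose 4 values in one genotype all lay above the 4 of the other. RAP identifiers carry the chromosome number after Os and are numbered along the chromosome. Chromosomes and neighbours were read from the identifiers.

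A further class was defined after the data were examined. A gene was termed near absent in one genotype if it was under 0.1 FPKM in all 4 of its libraries and at least 1 FPKM in all 4 libraries of the other. The alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter and a filter at 5 FPKM, median-of-ratios and quantile rescaling, the replicate number as a block, library quality weights, a robust variance prior, a fold threshold and leaving out each library. A count test was not run because the values are FPKM estimates and whole reads were not recovered. All 35 splits of the 8 libraries into 4 and 4 were refitted. No pair of libraries looked like one library under a pair of names: among the 27000 genes above 0 in all libraries, at most 0.0074% of values were identical between 2 libraries.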

Results

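The series asked what changes in the transcriptome of young rice inflorescences when OsG1L2 is mutated. OsG1L2 belongs to the ALOG family, plant-specific nuclear proteins, and the series title places it and OsG1L1 in the control of inflorescence branching. RNA was sequenced from dissected meristems at early stages of panicle development, from 4 osg1l2 libraries and 4 wild type libraries. The deposited FPKM values summed to between 218558 and 231675 per wild type library and between 213940 and 221906 per osg1l2 library. Between 17960 and 18334 genes reached 1 FPKM in a library, and the 10 most abundant genes took between 4.54% and 5.28% of the summed FPKM.

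The libraries separated by genotype. The first principal component of log2(FPKM + 1) carried 40.5% of the variance, with every wild type library at -11.5 or below and every osg1l2 library at 13.2 or above. Spearman correlations across the tested genes ranged from 0.966 to 0.986 between libraries of one genotype and from 0.957 to 0.975 between genotypes. The second component carried 17.9% of the variance and set wild type replicate 2, at -28.4, apart from the other wild type libraries, which lay between 4.87 and 10.8.

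**Figure D1:**
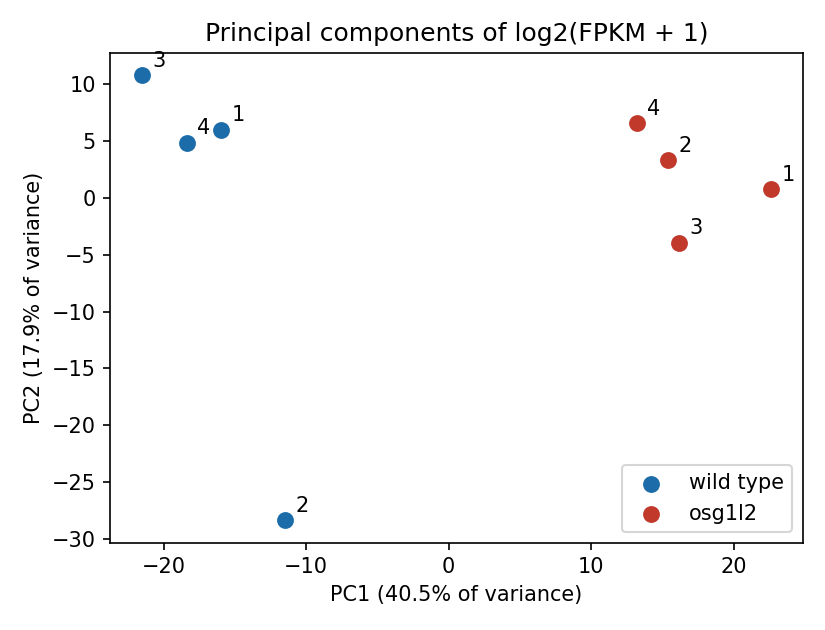
Principal components of log2(FPKM + 1) over 18254 tested genes, with PC1 on the x axis and PC2 on the y axis (share of variance in the axis labels); each point is a library, coloured by genotype and numbered by replicate. The genotypes separate along PC1, and wild type replicate 2 lies at -28.4 on PC2.

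The comparison of osg1l2 with wild type asked which transcripts differ between the genotypes. Of 18254 genes, 352 (1.93%) passed the test: 164 were higher in osg1l2 and 188 were lower (limma on log2(FPKM + 1), adjusted p under 0.05). All 352 had their 4 values in one genotype above the 4 of the other. The call and the separation rest on the same values, so this is no separate support. Across the tested genes 2153 (11.8%) were separated in this way, against 2.86% by chance. After median-of-ratios rescaling of the libraries the split turned to 205 higher and 137 lower, and after quantile normalization to 210 higher and 130 lower, so the excess of lower genes was not kept under these scalings. It was not kept either with no filter on low values (225 higher, 205 lower), with the replicate number as a block (82 higher, 70 lower) or without some single libraries. The higher genes had a median log2 fold change of 0.62, and 53 of them rose by at least 1 on the log2 scale. The lower genes had a median of -0.44, and 20 of them fell by at least 1. At a log2 change of at least 2 there were 21 higher genes and 3 lower genes. Most of the lower genes, 110 of 188, and 65 of the 164 higher genes changed by less than 0.5.

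The count changed when single libraries were left out. Such fits have fewer libraries and so less power, and a lower count need not reflect the library left out. Lower genes were in excess without wild type replicate 2 (826 genes, 293 higher and 533 lower), without osg1l2 replicate 2 (240, 113 and 127) and without osg1l2 replicate 4 (230, 103 and 127). Higher genes were in excess without wild type replicate 1 (155 genes, 90 higher and 65 lower), wild type replicate 3 (179, 100 and 79) or wild type replicate 4 (163, 88 and 75). The same held without osg1l2 replicate 1 (163, 84 and 79) or osg1l2 replicate 3 (184, 99 and 85).

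**Figure D2:**
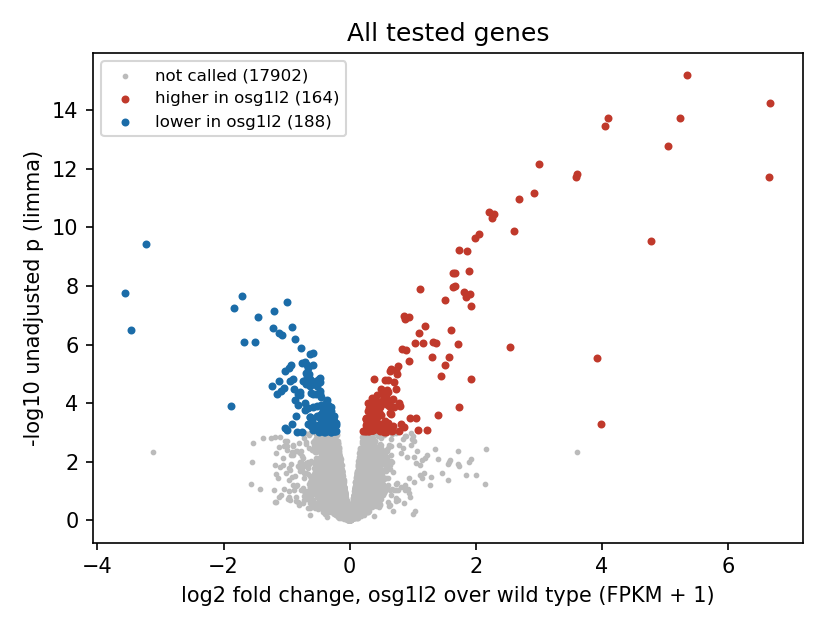
Each point is 1 of the 18254 tested genes; the x axis is the log2 fold change of osg1l2 over wild type on FPKM + 1 and the y axis is minus log10 of the unadjusted limma p. Of the 164 genes higher in osg1l2, 21 lie at a log2 change of at least 2, against 3 of the 188 lower genes.

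Changed genes were found at every level of expression. Among genes with a mean of 1 to 5 FPKM, 184 of 8784 passed the test (2.09%), with a median absolute log2 change of 0.58. Among genes of 5 to 20 FPKM, 1.72% of 7216 passed, with a median of 0.49. Among genes of 20 to 100 FPKM, 1.76% of 2046 passed, with a median of 0.33. Of the 208 genes at 100 FPKM or more, only 8 passed (3.85%), 1 higher and 7 lower, with a median of 0.41.

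The 2 largest rises were of genes near 0 in wild type. Os01g0537250, on chromosome 1 by its identifier, averaged 0.109 FPKM ± 0.053 (SD, n = 4) in wild type and 112.6 FPKM ± 11.7 (SD, n = 4) in osg1l2. Its log2 fold change was 6.67 with a standard error of 0.075 and an adjusted p of 5.2e-11 in limma. Os02g0517421, on chromosome 2, was listed at 0 in all 4 wild type libraries. In osg1l2 its values were 90.9, 125.5, 75.6 and 116.9 FPKM (limma adjusted p = 3.4e-09). The 2 largest falls were of genes moderately expressed in wild type. Os07g0153150, on chromosome 7, fell from 15.4 FPKM ± 1.12 (SD, n = 4) in wild type to 0.449 FPKM ± 0.521 (SD, n = 4) in osg1l2, a log2 fold change of -3.56 with a standard error of 0.20 (limma adjusted p = 1.1e-05). Os04g0602250, on chromosome 4, was at 5.81, 9.07, 19.8 and 9.59 FPKM in the wild type libraries and was listed at 0 in all 4 osg1l2 libraries (limma adjusted p = 0.00013). The sizes of these folds depend on the pseudocount: at 0.1 in place of 1 the log2 fold changes were 9.11 for Os01g0537250 and -5.32 for Os07g0153150, and the authors' deposited table, which shows no pseudocount, gives 10.4 and -5.57. For each of these 4 genes an exact two-sided permutation test of 4 against 4 libraries gave p = 0.0286, the smallest that this design allows. The naming rule required full separation of the genotypes, which fixes this value in advance, so it adds no support.

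A class of 28 genes was near absent in one genotype and expressed in the other. Of these, 27 were under 0.1 FPKM in every wild type library and at 1 FPKM or more in every osg1l2 library, and 1 showed the opposite. The 27 genes averaged between 1.12 and 102.3 FPKM in osg1l2, with a median of 3.81, and 7 of them reached 10 FPKM. Their highest osg1l2 library exceeded the lowest by a median of 1.26 times. In wild type, 14 of the 27 were listed at 0 in all 4 libraries, a value that can also come from a failed estimate. The 28 genes lay on 11 chromosomes, and no chromosome held more than 6. Chromosome 4 held 6 and chromosome 11 held 5, where 1558 and 947 of the 18254 tested genes lay. Their spread over the chromosomes was not tested. All 23 of the 28 genes that reached the test's level filter passed it (limma). The definition of the class makes this nearly certain, so it adds no support. Without wild type replicate 2 the class held 33 genes. Leaving out a library removes a condition of the class, so this count could not fall below 28.

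**Figure D3:**
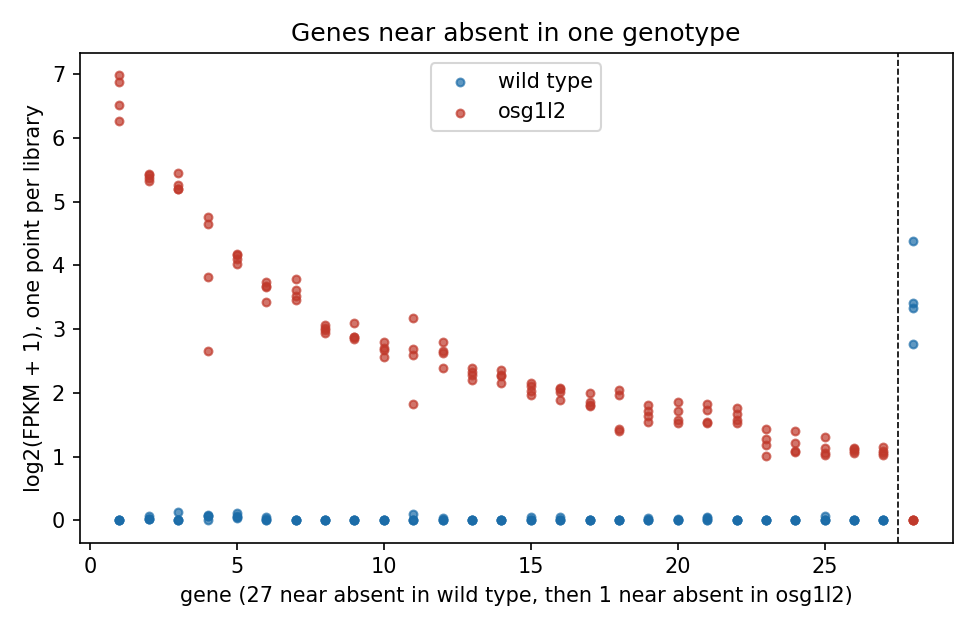
Each position on the x axis is 1 of the 28 genes near absent in one genotype, ordered by level; the y axis is log2(FPKM + 1), with one point per library (4 wild type and 4 osg1l2 points per gene). In 27 genes the osg1l2 libraries lie above and the wild type libraries near 0, and the dashed line sets off the 1 gene with the opposite pattern.

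The authors' own comparison was set beside these calls. The q-value in the authors' deposited table was under 0.05 for 760 entries, 331 higher and 429 lower in osg1l2. The smallest q-value in the authors' deposited table, 0.0024, was shared by 442 entries, so they cannot be ranked by it. Among entries above 0 in both genotypes that passed q, the authors' deposited table gave a median log2 fold change of 0.65 for the higher genes and -0.70 for the lower genes. Of 2218 entries at 0 in exactly 1 genotype in the authors' deposited table, 1175 were at 0 in wild type and 1043 in osg1l2. Of these, 32 passed q, and all 32 were at 0 in wild type.

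Over the 18199 genes that were tested and are also in the authors' deposited table, fold changes from the 2 sources had a Spearman correlation of 0.92 across 18181 genes with finite values; genes are not independent replicates. Both sources called 198 genes, 98 higher and 100 lower, with the same direction in all 198. Independent lists of these sizes would share 2.21 higher and 3.52 lower genes, but both sources rest on the same libraries. The FPKM test alone called 153 genes, with a median absolute log2 change of 0.35, against 0.63 for the genes called by both. The authors' deposited table alone called 390 genes, and 233 of these (59.7%) had an unadjusted limma p under 0.05 in the FPKM test. Of the named genes, the authors' deposited table gave q = 0.0024 for Os01g0537250, Os02g0517421 and Os07g0153150, and q = 0.15 for Os04g0602250.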

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

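The refits of other splits were planned before the data were examined, but the prediction for that test was written after they had been run once.

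Wild type replicate 2 stood apart from the other wild type libraries on the second principal component, at -28.4 against 4.87 to 10.8. Its gap to the nearest library was 0.849 of the group's range, above the critical value of 0.829 for 4 values. It was the only flag among 22 groups of 4 values. For independent values chance flags about 1 in 20 groups, so 1 flag among 22 is about what chance gives. The component is fitted to these libraries and the groups share libraries, so that rate need not hold here. Library quality weights gave this library the lowest weight, 0.404.

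A random assignment of libraries to genotypes was tested by refitting all 35 splits of the 8 libraries into 4 and 4. Only 1 of the 35 splits, the real one, gave as many as 352 called genes, and the highest other split gave 1. This argues against a random assignment of these libraries as the origin of the count. With 35 splits the real one can rank no better than 1 of 35. The other splits mix the genotypes, which widens the spread within their groups, so their low counts do not measure false calls.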

How the results depend on the processing

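Apart from left-out libraries, the count of 352 called genes moved by over 1.5 times under 4 of the alternatives fixed before the data were examined. A mean of at least 5 FPKM gave 153 (60 higher, 93 lower), all of them among the 352, with fewer genes tested. Library quality weights gave 1097 (389 higher, 708 lower), including all 352. A log2 change of at least 1 gave 73 by construction (53 higher, 20 lower). The replicate block gave 152 (82 higher, 70 lower), of which 130 were among the 352. Replicate numbers did not pair the libraries: deviations from the genotype means correlated at 0.069, -0.017, -0.091 and -0.12 for replicates 1 to 4, and not every library correlated best with its own number. Leaving out each library gave 155 to 826 genes (84 to 293 higher, 65 to 533 lower), over 1.5 times away from 352 in each fit except the one without osg1l2 replicate 2 (240). Of these, fits without wild type replicate 2 kept 339 of the 352 and fits without wild type replicate 1 kept 149. The cause was not tested for the block, the weights or the left-out libraries. The other settings fixed before the data were examined gave totals from 340 to 430, and leaving out the near-absent genes, added after, gave 287, but rescaling, like the block, no filter on low values and 5 of the 8 left-out libraries, turned the excess of lower genes into one of higher genes: median-of-ratios gave 59.9% higher and quantile normalization 61.8%, against 46.6%. Median-of-ratios rescaling moved the median log2 change of all tested genes from -0.037 to -0.0022, and quantile normalization to -0.0033. The log2 fold changes of the named genes were larger in size at lower pseudocounts, 9.11 for Os01g0537250 and -5.32 for Os07g0153150 at 0.1. The 4 named genes kept direction and significance in every alternative that tested them, with adjusted p in limma up to 2.3e-07 for Os01g0537250, 1.6e-06 for Os02g0517421, 0.0013 for Os07g0153150 and 0.0031 for Os04g0602250. For the 28 near-absent genes, settings added after seeing the data gave 14 at limits of 0.05 and 2 FPKM and 62 at limits of 0.2 and 0.5 FPKM. Without each library there were 29 to 33. Stricter limits can only lower this count, while looser limits or a left-out library can only raise it, so these directions were fixed in advance. In the authors' deposited table, 246 entries passed q with a log2 change of at least 1, and 536 passed q under 0.01. A count test and the gene lists gave no value. Depth is unknown, so what it limits could not be assessed.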

Other observations

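The tests of other splits for near-absent genes and of opposite neighbours were written down before their results were seen. So were those of near-absent genes among adjacent pairs and of similarity between uncalled neighbours. For other splits, opposite neighbours and uncalled neighbours, the value met the limit written beforehand for arguing against the explanation. A more cautious reading replaced those limits, so these explanations are left open below. All other tests in this part were chosen after.

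Called genes were unevenly spread over the chromosomes. On chromosome 11, 41 of 947 tested genes were called (4.33%), 24 higher and 17 lower, against 1.80% on the other chromosomes (two-sided Fisher's exact test, odds ratio 2.47, p = 1.2e-06, adjusted p = 1.5e-05 over 12 chromosomes). On chromosome 12, 3.17% of 1010 were called, against 1.86% elsewhere (odds ratio 1.73, adjusted p = 0.038), and no other chromosome passed 0.05. Neighbouring calls are not independent, so these p-values are too small. With each library left out in turn the odds ratio for chromosome 11 ranged from 1.65 without wild type replicate 2 (Fisher's exact p = 0.00029) to 3.88 without wild type replicate 4, and it was 3.74 without wild type replicate 1. Under the other alternatives this odds ratio ranged from 1.68 with library quality weights to 4.39 at a log2 change of at least 1.

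Called genes also lay beside each other. Among tested genes in identifier order, 35 pairs of neighbours were both called, against a mean of 6.75 and a highest value of 20 in 10000 random placements (one-sided permutation p = 0.0001, the smallest these placements can give). The 2 genes moved in the same direction in 23 of the 35 pairs (65.7% against 50.2% expected, exact binomial p = 0.090). That test treats pairs as independent, but pairs in a run share a gene, and the longest run held 3 called genes. The count of 35 pairs argues against random placement. Without the near-absent genes 26 pairs were found against a highest random value of 18, which argues against those genes as the whole cause. Among identifiers that end in 00 alone there were 21 pairs against a highest random value of 16. General similarity of neighbouring genes stays open: 17575 adjacent pairs of uncalled genes had fold changes correlated at 0.041 (Spearman), but only 3558 of the 18254 tested genes reached even an unadjusted limma p under 0.05, and the spread between libraries in the rest lowers any such correlation, so this value excludes nothing. Reads shared between overlapping gene models or tandem copies, local chromatin and linked sequence differences between the lines stay open, as untested. The size of the excess depended on the libraries: the ratio of observed to expected pairs was 5.17 with all of them, 1.87 without wild type replicate 2 (70 pairs against 37.4), 11.5 without wild type replicate 1, 9.16 without wild type replicate 3, 11.8 without wild type replicate 4 and 9.69 without osg1l2 replicate 1. It was 1.64 with library quality weights and 10.3 with the replicate number as a block. With a mean of at least 5 FPKM it was 3.26 (8 pairs against 2.45), and at a log2 change of at least 1 it was 34.8 (10 pairs against 0.288).

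The 27 genes near absent in wild type and expressed in osg1l2, against 1 gene with the opposite pattern, form the pattern most open to follow-up. Of the 35 splits of the libraries, 1, the real one, gave 28 such genes, and the highest other split gave 1; the limits of the class were set after seeing the real grouping, so this does not test chance independently. Mutant alleles that differ from the Nipponbare reference would lose reads in osg1l2. However, 96.4% of the genes (exact 95% interval 81.7% to 99.9%, which treats genes as independent) were near absent in wild type. This argues against lost reads of that kind as the origin of the class. The direction was known when this test was chosen, and sequence differences that add reads in osg1l2 were not tested. Reads moved between gene models by the quantification stay open: 17.9% of the 28 (exact 95% interval 6.06% to 36.9%) had a gene within 2 places that moved the other way by at least 0.5 times as many FPKM. The 51.1% of other tested genes is no baseline for this, since their smaller changes meet the limit more easily, and gene lengths, which scale FPKM, were not used here. The design has 1 mutant genotype, so activation after loss of OsG1L2 cannot be told apart from a difference between the lines that is unrelated to the mutation; both may contribute.

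Among the 23 near-absent genes that were tested, 43.5% had identifiers that do not end in 00, against 11.8% of the other tested genes (two-sided Fisher's exact p = 0.00014). The comparison was not matched on expression level, and the class was chosen on the same values. Of all 37859 identifiers, 21.1% do not end in 00. Such identifiers were 25.6% of all higher calls and 11.7% of all lower calls. Of the 28 near-absent genes, 14 passed q under 0.05 in the authors' deposited table, all 14 in the same direction. Both sources rest on the same libraries and the class is defined by its difference, so the shared direction adds no support.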
